A study of Mus musculus with 8 samples.

How the data were processed

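Hearts and spleens of mice under 4 treatments were profiled with 10x Genomics 3′ single-cell RNA sequencing, 1 library per treatment and organ, and animals of a group were pooled before loading per the labels' protocols. The deposited values were whole-number UMI counts per gene and barcode, made with Cell Ranger 3.0.2 for the heart and 4.0.0 for the spleen per the file headers, with no normalization. The mm10 build and Seurat 4.3.0 were named per the submitters' processing notes. Every deposited barcode held at least 500 UMIs, and any other filter applied before deposit is not given in the sources used here. Gene tables listed 31053 genes in the heart and 32285 in the spleen, so the organs were analysed apart and never compared numerically. Coordinates were taken by gene ID from GENCODE mouse release 21 (GRCm38, Ensembl 96).

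Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs. Scrublet, run in scanpy 1.11.5 on each library, removed 4, 4, 3 and 2 heart barcodes and 0, 0, 2 and 4 spleen barcodes (order Chow, HFD, L-NAME, HFpEF). The spleen caller marked so few of the cells that it has not worked, so clusters with markers of more than 1 class were set apart as mixed. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.5 (leidenalg 0.10.2, seed 0) gave the clusters of each organ. Clusters were named from markers of 15 heart and 16 spleen classes fixed before the data were examined. A name needed at least 3 markers detected in 20% of cells and a mean log2 fold of at least 0.5, and a cluster was mixed where a second class scored at least 1 with markers in 50% of cells. Folds were taken over the median cluster with 20 CPM added. Those thresholds were set after the data were seen, and they decide which clusters stay unnamed or mixed. No cluster could be named from the planned stem and multipotent progenitor markers, so cluster 21 replaced that class after the data were seen, as those markers were in a mean share of 0.282 of its cells (at least 0.2 was asked). Its best score was for erythroid markers (2.39), with 0.72 for stem and progenitor markers. A cluster was left unnamed where its top 10 genes held more markers of another class.

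UMIs were summed per library over the macrophage-like class in the heart and cluster 21 in the spleen and expressed as CPM. A ratio added 0.5 UMI to both libraries, so it differs slightly from the quotient of CPM values, and its 95% interval is the exact conditional (Clopper-Pearson) one. Intervals of shares are exact binomial (Clopper-Pearson), those of CPM exact Poisson, and a count of 0 allows up to 3 counts. All cover counting error only, and no interval holds the variation among animals, cells or library preparations. Hence no p-value, standard error or number of changed genes is given. Deeper libraries have narrower intervals, and heart macrophage-like cells rested on 419207 to 1203805 UMIs per library.

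Genes were named by a rule fixed beforehand. Genes needed at least 100 UMIs over both libraries and a UMI in at least 5% of class cells of either, and were ranked by the interval bound nearest to 1. The first 10 on each side were named in HFpEF against Chow and the first 6 in each other comparison. Mitochondrial, ribosomal protein, haemoglobin and immunoglobulin genes, predicted genes and markers of other classes were left out of that ranking. A class with under 50 cells in either library gave none. Some genes that met the rule are not reported here. As examples, list members with the 2 largest UMI totals and the 2 intervals farthest from 1 were eligible. Other spleen genes given for cluster 21, markers of other cells, and Cd36 in endothelial-like cells were chosen after their values were seen. In total, 30 gene lists of 4 to 22 genes (384 genes) were fixed beforehand. Members with at least 10 UMIs over both libraries were counted as higher or lower, and a list's median log2 ratio was placed among 10000 random lists of the same size matched on expression. Among eligible heart genes the median log2 ratio was 0.04, −0.08 and 0.04 for HFD, L-NAME and HFpEF against Chow. Comparisons against Chow share that library, so they were not correlated with each other.

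Shares of cells with a UMI used cells thinned to 500 UMIs, which left out no kept cell. Alternatives fixed beforehand numbered 11. They were minima of 1000 UMIs or of 250 UMIs with 100 genes, a limit of 10% mitochondrial UMIs, doublets kept, Leiden resolution 1, means of per-cell shares, totals without abundant gene groups, thinning of class cells to 500 UMIs, list members with at least 50 UMIs, and shares at 1000 UMIs or not thinned. Another 3 were chosen after seeing the data, a limit of 40% mitochondrial UMIs, removal of the highest doublet scores at 0.8% per 1000 barcodes, and equal weights for the heart macrophage clusters with at least 10 cells in each library (2, 4 and 7), which leaves out cluster 10 and so alters membership as well as weights. Which list values were recomputed was also settled after seeing a fuller set with more reversals, and is limited to those the text reports. Interval and list steps were tested on simulated counts for HFpEF against Chow. These were Poisson draws around class means, the same model as the intervals, so they check the calculation and not its fit to these data. The clumping of UMIs in single cells was not simulated. In the heart (1535 genes, 200 of them changed) intervals held the true ratio for 95.9% of genes, and 97.1% of 2-fold and 100% of 4-fold changes were called in the right direction. In the spleen (4308 genes) these were 95.7%, 99.0% and 100%. Intervals excluded 1 for 6.8% of unchanged genes in the heart and 4.6% in the spleen. A raised list reached the 100th percentile in both organs, and 4 of 40 unchanged lists in the heart and 1 of 40 in the spleen fell outside the 2.5th to 97.5th percentiles, where 2 of 40 are expected. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9 were used.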

Results

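Single-cell RNA sequencing was performed on hearts and spleens of adult male C57BL/6J mice, an inbred laboratory strain, aged 12 to 15 weeks. Mice received control chow (Chow), a high-fat diet (HFD), L-NAME, an inhibitor of nitric oxide synthases, or both together for 5 weeks. The combined treatment is used to model heart failure with preserved ejection fraction and is named HFpEF, as in the labels. Cells of 5 animals per group and organ were pooled before loading, which left 1 library for each of the 8 groups. Heart cells were enriched with beads for F4/80, a macrophage surface antigen encoded by Adgre1, and spleen cells for cKIT, the receptor on blood stem and progenitor cells. Questions addressed were how heart macrophages differed after each treatment, with lipid metabolism of particular interest, and how blood progenitors of the spleen differed. With 1 library per group no difference could be tested against replicate spread. Values are given for both libraries with 95% intervals that cover counting error only, and every comparison is between libraries rather than conditions.

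Heart libraries held 11475 (Chow), 4935 (HFD), 15360 (L-NAME) and 795 (HFpEF) barcodes, with totals of 13001082, 10814254, 20616496 and 3516807 unique molecular identifiers (UMIs). Most of these barcodes carried mainly mitochondrial RNA. The median mitochondrial share was 99.0%, 87.5%, 98.9% and 37.4% of UMIs in the same order. After the limit of 20% mitochondrial UMIs and the other filters, 434, 638, 329 and 285 heart cells were kept. Spleen libraries kept 14689, 18531, 8587 and 11610 cells of 14836, 18797, 8911 and 11935 barcodes, and their totals ran from 30920251 to 41975744 UMIs. Kept cells had median depths of 2891, 4838, 3493 and 6168 UMIs in the heart and 1892, 1613, 2534 and 2411 UMIs in the spleen.

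Macrophage-like cells made up a smaller share of the kept heart cells in each treated library than in the Chow library, by an amount that depended on the mitochondrial limit. Macrophage-like cells were 34.6% of kept cells in the Chow library (95% exact binomial interval 30.1 to 39.2%), 28.2% in HFD, 27.7% in L-NAME and 23.9% in HFpEF (19.0 to 29.2%). The share ratio of HFpEF to Chow was 0.690 (95% interval 0.511 to 0.925), and the intervals of the HFD ratio (0.654 to 1.02) and the L-NAME ratio (0.610 to 1.04) included 1. With the mitochondrial limit at 40% the shares were 26.6%, 20.1%, 18.9% and 20.7%, lowest in L-NAME, so the HFpEF library does not stand apart from the other treated libraries. B cell-like cells were 2.53%, 6.43%, 5.17% and 6.67% of kept cells, with ratios to Chow of 2.54 (1.28 to 5.47) in HFD and 2.63 (1.19 to 6.12) in HFpEF. Endothelial-like cells were 30.4%, 22.7%, 19.8% and 22.5%, and 54.4%, 44.9%, 52.1% and 40.4% with the limit at 40%. Monocyte-like cells were 0.691%, 2.98%, 1.52% and 1.05%, and fibroblast-like cells 1.84%, 2.35%, 1.22% and 3.86%. Clusters with markers of more than 1 class held 25.3%, 31.7%, 36.2% and 35.4% of kept cells, and 8.86%, 18.6%, 11.6% and 18.5% with the limit at 40%. At 20%, unnamed clusters held 4.61%, 5.64%, 8.51% and 6.67%. F4/80 bead enrichment and the mitochondrial limit, which removed 63.5% of HFpEF and 96.1% of Chow barcodes, can both set these shares. After thinning to 500 UMIs, Adgre1 was detected in 23.3%, 18.3%, 17.6% and 27.9% of macrophage-like cells (median depths 3201, 5985, 4381 and 7813 UMIs), and in 72.7%, 82.8%, 70.3% and 85.3% without thinning. Among endothelial-like cells it was seen after thinning in 0 of 132 (Chow), 0 of 145 (HFD), 0 of 65 (L-NAME) and 0 of 64 (HFpEF) cells.

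Clusters 2, 4, 7 and 10 formed the macrophage-like class of 150, 180, 91 and 68 cells. Cluster 4, led by genes that include Lyve1, Folr2 and F13a1, held 38.7%, 35.0%, 22.0% and 32.4% of these cells. Cluster 10, led by Retnla and MHC class II genes with Ccr2, held 2.00%, 7.22%, 13.2% and 8.82%. Its score was 2.91 for macrophage markers and 2.11 for dendritic cell markers, so dendritic cells within it are not set apart. The remaining clusters, 2 and 7, held 43.3% and 16.0% of the class in Chow and 33.8% and 25% in HFpEF. Median mitochondrial shares within the class were 14.2%, 11.9%, 14.6% and 8.00%.

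In macrophage-like cells of the HFpEF library, cell cycle and PPAR target genes were higher than in the Chow library, and markers of resident cardiac macrophages and heat shock genes were lower. Heat shock genes were lower in endothelial-like cells too. Mki67, a proliferation marker, stood at 135 against 28.4 UMIs scaled to a common total (CPM), 4.63-fold higher (95% interval 2.73 to 8.86). Top2a, a topoisomerase of dividing cells, stood at 160 against 24.7 CPM, 6.28-fold higher (3.64 to 12.6), although 1 cell held 42.7% of its UMIs in HFpEF and 92.3% in Chow. Lyve1, a hyaluronan receptor of resident cardiac macrophages, stood at 336 against 901 CPM, 2.68-fold lower (2.28 to 3.17). The chemokine Ccl8 was 8.2-fold lower (5.58 to 12.9; 43.5 against 362 CPM), and 1 cell held 45.6% of its UMIs in the Chow library.

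By the rule for named genes, the 10 leading higher genes in HFpEF against Chow also included AC160336.1 (8.22-fold), Hnrnpa0 (8.23-fold), Ndufa3 (5.38-fold), Rnaset2a (5.22-fold), AY036118 (4.65-fold), Stmn1 (4.64-fold) and Hmgb2 (3.40-fold). Rnaset2a has a near-identical copy, Rnaset2b, and their split counts are uncertain. Of the 10, 6 were also higher in endothelial-like cells, with intervals above 1, and the other 4, Top2a, Mki67, Stmn1 and Hmgb2, were lower there. The leading lower genes also included Fcna (4.98-fold), Gadd45g (3.44-fold), Vsig4 (3.27-fold), Ltc4s (2.58-fold), Hsp90aa1 (2.29-fold), Wfdc17 (2.25-fold), Ctsd (2.20-fold) and Ccl6 (2.09-fold). Of these 10, Hsp90aa1 and Ctsd were also lower in endothelial-like cells. On the mm10 (GRCm38) assembly, Mki67 (ENSMUSG00000031004) lies on chromosome 7 from 135689784 to 135716361 and Top2a (ENSMUSG00000020914) on chromosome 11 from 98992943 to 99024189. Lyve1 (ENSMUSG00000030787) lies on chromosome 7 from 110850607 to 110863239, Ccl8 (ENSMUSG00000009185) on chromosome 11 from 82115185 to 82116799, and Hnrnpa0 (ENSMUSG00000007836) on chromosome 13 from 58125879 to 58128556. AC160336.1 (ENSMUSG00000115801), a long intergenic noncoding RNA, lies on chromosome 14 from 44544055 to 44637201. Counts are per whole gene, so exons and untranslated regions were not told apart.

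**Figure D1:**
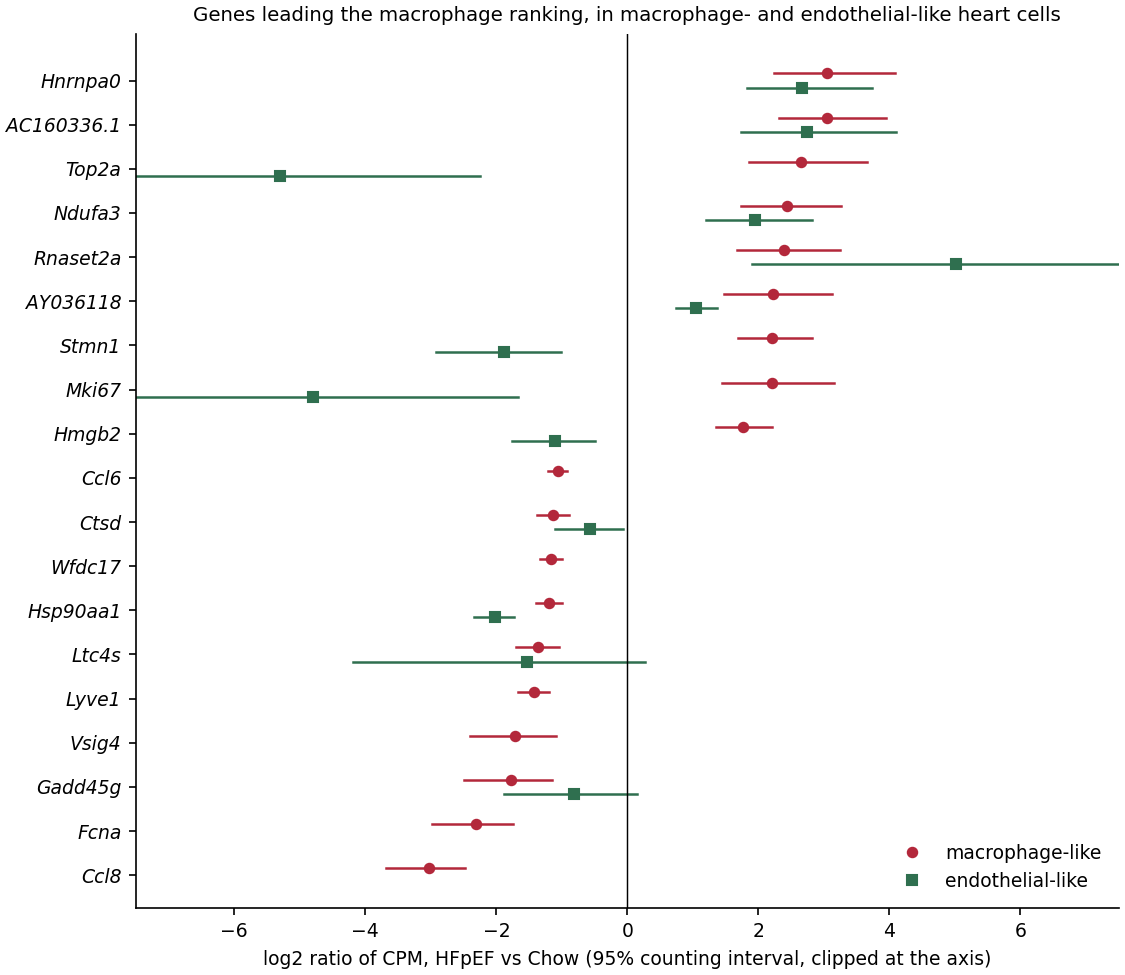
Fold ratios (log axis) of 19 of the 20 leading genes in HFpEF against Chow, in macrophage-like cells and endothelial-like cells of the heart, with exact 95% intervals for counting error. Endothelial values with under 10 UMIs in both libraries together are not drawn. Hnrnpa0 stands at 8.23-fold in macrophage-like cells and 6.36-fold in endothelial-like cells, whereas Lyve1 is 2.68-fold lower in macrophage-like cells.

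The G2 and M phase list stood at 1721 CPM in HFpEF against 330 CPM in Chow, a ratio of 5.20 (4.44 to 6.15). All 22 measured members were higher in this comparison, 21 with intervals above 1, and the list median lay at the 100th percentile of 10000 random lists of matched expression. Ube2c stood at 123 against 5.70 CPM, from 79 and 3 UMIs, 18.6-fold higher (7.12 to 107). The log2 ratio of 2.38 was 1.57 with cells thinned to 500 UMIs. A few cells held most of these UMIs, the top 3 cells 81.8% of 1107 in HFpEF and 50% of 174 in Chow. In endothelial-like cells the same list was lower in HFpEF, at 598 against 1218 CPM, but its log2 ratio of −1.03 was 0.02 with the mitochondrial limit at 40%. The endothelial-like class of the Chow library also held 2407 haemoglobin UMIs, against 2 in HFpEF. S phase genes stood at 541 against 222 CPM, a ratio of 2.43 (1.97 to 3.03), with 16 of 16 measured members higher.

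Among lipid metabolism lists, PPAR target genes and fatty acid uptake and storage genes were higher in macrophage-like cells of the HFpEF library. Both lists hold Cd36, Fabp4 and Plin2, so they are not separate results. The fatty acid oxidation list stood at 839 against 635 CPM, a ratio of 1.32 (1.15 to 1.52), with 15 of 19 members higher, 3 of them with intervals above 1, and a median at the 98.2nd percentile. Its log2 ratio of 0.40 turned to −0.37 when cells were thinned to 500 UMIs. Thinning left 500 UMIs in each of 68 (HFpEF) and 150 (Chow) cells, so that value has a wider counting interval, not given here. Etfb, an electron carrier of fatty acid oxidation, was 1.56-fold higher (1.03 to 2.43), and Acads, a short-chain acyl-CoA dehydrogenase, 2.25-fold higher (1.13 to 5.09). PPAR target genes had a ratio of 1.43 (1.30 to 1.56; 99.0th percentile), with Ucp2 1.53-fold higher (1.36 to 1.74) and Fabp4 2.33-fold lower (1.45 to 3.89). The fatty acid uptake and lipid storage list had a ratio of 1.24 (1.12 to 1.38). Within it Lpl, which encodes lipoprotein lipase, was 3.5-fold higher (2.33 to 5.55), and Cd36, a fatty acid transporter that was also 1.86-fold higher in endothelial-like cells, was 1.92-fold higher (1.51 to 2.47). Fatty acid synthesis genes, with 57 and 52 UMIs, had a ratio of 0.898 (0.606 to 1.33). Cholesterol synthesis and export genes had a ratio of 0.699 (0.679 to 0.719), of which Apoe made up 97.6% of UMIs, and a log2 ratio of 0.04 without it. Glycolysis genes had a ratio of 1.09 (1.00 to 1.18), and nuclear genes of oxidative phosphorylation 1.06 (1.01 to 1.12).

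Among immune lists, inflammatory cytokine and inflammasome genes had a ratio of 1.32 (1.26 to 1.40), with 15 of 19 members higher and a median at the 99.9th percentile. Nfkbia, an inhibitor of NF-kB, was 1.38-fold higher (1.21 to 1.58), and Il1a had 30 UMIs in HFpEF and 0 in Chow. Markers of other cells were also higher within this class, neutrophil markers at 908 against 468 CPM, T cell markers at 174 against 28.4 CPM and NK cell markers at 155 against 62.6 CPM. Il1b made up 75.1% of the niche and haematopoietic signal list, whose ratio was 1.95 (1.70 to 2.24) and whose log2 ratio was 0.13 without it, and 3 cells held 52.1% of that list's UMIs in HFpEF. MHC class II genes had a ratio of 1.33 (1.30 to 1.35), with H2-Eb1 1.69-fold higher (1.60 to 1.79). Genes of recruited macrophages and monocytes had a ratio of 1.16 (1.10 to 1.23). Of that list's UMIs, Il1b held 565 of 2859 in HFpEF and 191 of 2014 in Chow. Interferon response genes had a ratio of 0.889 (0.837 to 0.945), with 7 of 16 members higher, and their log2 ratio of −0.17 turned to 0.08 after thinning to 500 UMIs.

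Of the 12 resident cardiac macrophage genes 10 were lower in HFpEF, 8 with intervals below 1, and the list ratio was 0.735 (0.703 to 0.769; 0.0th percentile). F13a1 was 1.63-fold lower (1.47 to 1.80), whereas Mrc1 was 1.10-fold higher (0.970 to 1.25). Lipid-associated macrophage genes had a ratio of 0.742 (0.704 to 0.782), with Ctsb, a lysosomal protease, 1.37-fold lower (1.27 to 1.48). Efferocytosis genes, which serve the uptake of dying cells, had a ratio of 0.712 (0.684 to 0.740), antioxidant response genes 0.735 (0.716 to 0.754), and pro-fibrotic and growth factor genes 0.722 (0.663 to 0.786). Unfolded protein response genes had a ratio of 0.844 (0.792 to 0.899) and heat shock genes 0.620 (0.594 to 0.647). In endothelial-like cells the heat shock ratio was 0.382 (0.360 to 0.404), so this difference was not particular to macrophage-like cells. Heat shock genes also respond to tissue handling, so handling of each heart is open beside the treatment. Mitochondrially encoded genes had a ratio of 0.593 (0.586 to 0.600). Dissociation and immediate early genes had a ratio of 1.03 (1.01 to 1.06), a log2 ratio of 0.05 that was −0.03 as a mean over cells, 0.00 on totals without the most abundant gene groups and −0.13 after thinning.

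Lists chosen for the spleen gave, in the same cells and comparison, ratios of 1.08 (1.00 to 1.17) for stem cell quiescence, 1.06 (0.990 to 1.14) for myeloid priming, 2.06 (1.55 to 2.80) for lymphoid priming and 1.06 (0.986 to 1.15) for cytokine receptors and adhesion. The megakaryocyte and erythroid priming ratio of 0.702 (0.684 to 0.721) was 85.0% Apoe. Immunoglobulin constant genes, from B cells, had a ratio of 1.49 (1.17 to 1.91). Haemoglobin genes had 2 UMIs in HFpEF and 1 in Chow.

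**Figure D2:**
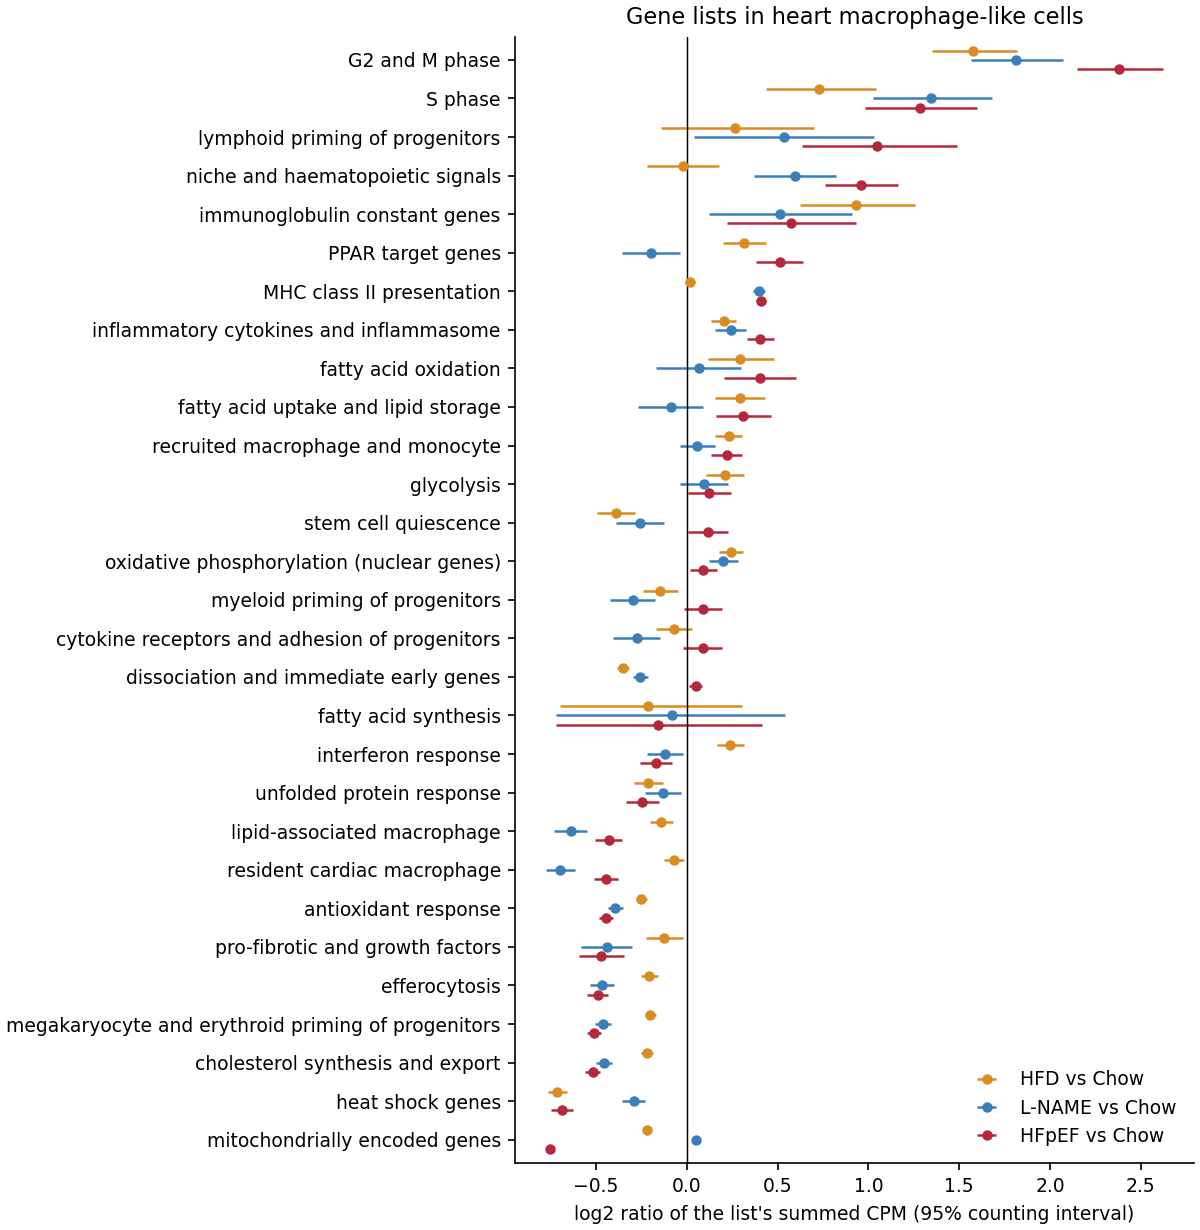
Log2 ratios to the Chow library of the gene lists in macrophage-like cells of the heart, for the HFD, L-NAME and HFpEF libraries, with exact 95% intervals for counting error. The G2 and M phase list stands at 1.58, 1.81 and 2.38 and the heat shock list at −0.71, −0.29 and −0.69. Fatty acid oxidation values of 0.30 (HFD) and 0.40 (HFpEF) turned to −0.02 and −0.37 with cells thinned to 500 UMIs. Thinned values rest on far fewer UMIs.

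Compared to the Chow library, macrophage-like cells of the HFD library had lower heat shock genes and higher cell cycle and PPAR target genes. Hsp90aa1, a cytosolic chaperone, stood at 555 against 1162 CPM, 2.09-fold lower (1.87 to 2.34), and Hspb1, a small heat shock protein, was 2.76-fold lower (2.09 to 3.65). Lpl stood at 169 against 53.1 CPM, 3.13-fold higher (2.13 to 4.90). The chemokine Ccl4 was 2.13-fold higher (1.82 to 2.51). All 6 leading lower genes, namely Hspb1, Hsp90aa1, Hsph1, Hspa1a, Stip1 and Hspa8, encode heat shock proteins or their partners, and the heat shock list ratio was 0.610 (0.588 to 0.633), with 10 of 10 members lower. In endothelial-like cells that ratio was 0.373 (0.355 to 0.392), so the lower heat shock genes were not particular to macrophage-like cells. The leading higher genes also included Hnrnpa0 (5.31-fold), Ndufa3 (4.2-fold), Lyz1 (3.97-fold) and Stmn1 (3.05-fold). In endothelial-like cells Hnrnpa0 was also higher (4.5-fold), as was Ndufa3 (2.94-fold), whereas Stmn1 was lower there (log2 −1.46). The log2 ratio of Stmn1 turned from 1.61 to −0.08 after thinning.

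Fatty acid oxidation genes had a ratio of 1.23 (1.08 to 1.40) in HFD against Chow, with 15 of 19 members higher, and a log2 ratio of 0.30 that turned to −0.02 after thinning. Cpt1a, which admits fatty acids to mitochondria, was 1.72-fold higher (1.05 to 3.07). PPAR target genes had a ratio of 1.25 (1.15 to 1.36) and fatty acid uptake genes 1.23 (1.12 to 1.35). The G2 and M phase ratio was 2.99 (2.55 to 3.53), with 21 of 21 members higher, and 3 cells held 62.5% of its 1189 UMIs in HFD. The S phase ratio was 1.66 (1.35 to 2.06). Recruited macrophage genes had a ratio of 1.17 (1.12 to 1.24), with Ccr2 2.61-fold higher (2.00 to 3.5), although the log2 ratio of 0.23 turned to −0.06 with clusters weighted equally. Markers of other cells were also higher within this class, monocyte markers, Ccr2 among them, at 399 against 169 CPM, neutrophil markers at 817 against 468 CPM and T cell markers at 65.6 against 28.4 CPM. Dissociation and immediate early genes were lower in 15 of 15 members (ratio 0.785, 0.767 to 0.803). Like the heat shock genes, they also respond to tissue handling, which is open beside the diet. Resident macrophage genes had a ratio of 0.953 (0.918 to 0.990), within which Vsig4 was 1.89-fold higher (1.48 to 2.48). Interferon response genes had a ratio of 1.18 (1.12 to 1.24) and a log2 ratio of −0.05 without Ifi27l2a.

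In macrophage-like cells of the L-NAME library, resident macrophage genes were lower and cell cycle genes were higher than in Chow. Lyve1 stood at 322 against 901 CPM, 2.79-fold lower (2.31 to 3.41). All 12 resident macrophage genes were lower, 10 with intervals below 1 (ratio 0.617, 0.585 to 0.652). Cluster 4, led by genes that include Lyve1, held 22.0% of the class in L-NAME and 38.7% in Chow. The values given here do not tell that mix apart from lower expression per cell. Markers of other cells also differed within this class, cardiomyocyte markers at 391 against 171 CPM, endothelial markers at 279 against 127 CPM and neutrophil markers at 11.9 against 468 CPM. Retnla, a secreted resistin-like protein, stood at 2185 against 567 CPM, 3.85-fold higher (3.38 to 4.41), but it was seen in 16.5% of cells in L-NAME and 16.0% in Chow, and 1 cell held 33.2% and 32.1% of its UMIs. The antiviral gene Rsad2 was 29.2-fold higher (12.4 to 122), with 77.9% of its 104 UMIs from 1 cell, and the histone gene Hist1h2ap had 142 UMIs against 1. The histone gene has near-identical copies, so its counts are uncertain. Stmn1 was 7.57-fold and Id2 3.66-fold higher. Ccl8 was 4.17-fold, Ninj1 2.29-fold, Ccl6 2.25-fold and Ctsd 2.18-fold lower. The G2 and M phase ratio was 3.51 (2.96 to 4.21) and the S phase ratio 2.54 (2.03 to 3.21), each with 13 of 13 members higher.

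MHC class II genes had a ratio of 1.32 (1.29 to 1.35) in L-NAME against Chow, and a log2 ratio of 0.40 that turned to −0.10 with clusters 2, 4 and 7 weighted equally and cluster 10 left out. Fatty acid oxidation genes had a ratio of 1.05 (0.891 to 1.23), not distinguishable from 1 at this depth. PPAR target genes had a ratio of 0.873 (0.780 to 0.976), and their log2 ratio of −0.20 turned to 0.33 with predicted doublets kept and to 0.39 with the highest doublet scores removed. Lipid-associated macrophage genes had a ratio of 0.642 (0.603 to 0.684), with Plin2, a lipid droplet coat protein, 2.07-fold lower (1.54 to 2.85). Interferon response genes had a ratio of 0.920 (0.860 to 0.984) with 12 of 17 members higher, and their log2 ratio of −0.12 turned to 0.03 after thinning and to 0.01 with clusters weighted equally. Niche and haematopoietic signals had a ratio of 1.51 (1.29 to 1.77), with Il1b 1.78-fold higher (1.48 to 2.16). Il1b held 271 of that list's 358 UMIs in L-NAME and 191 of 298 in Chow.

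HFpEF was also compared with each treatment alone. Against HFD, Rnaset2a (4.39-fold), AC160336.1 (3.48-fold), BC028528 (2.5-fold), Il1b (2.33-fold), Tuba1c (2.32-fold) and Btg1 (2.02-fold) led the higher genes. Il1b stood at 878 against 376 CPM, 1 cell held 34.2% of its UMIs in HFpEF, and its log2 ratio of 1.22 turned to −0.41 as a mean over cells and −0.23 after thinning. Mmp12, a macrophage elastase, was 8.43-fold lower (4.03 to 25.3) and Vsig4 6.20-fold lower (4.28 to 9.63), followed by Ccl8 (4.34-fold), Fcna (4.14-fold), Lyz1 (3.00-fold) and S100a6 (2.38-fold). The log2 ratio of Lyz1, −1.58, turned to 0.26 with the mitochondrial limit at 10%. Against L-NAME, AC160336.1 (5.48-fold), Rnaset2a (5.38-fold), Snrpf (4.75-fold), Hnrnpa0 (4.67-fold) and Rin2 (3.89-fold) were higher, and Rsad2 (29.2-fold), Hist1h2ap (3.80-fold), Dnajb1 (2.34-fold), Hsp90aa1 (2.27-fold), Wfdc17 (2.09-fold) and Dnaja1 (2.09-fold) were lower. Fatty acid oxidation and G2 and M phase log2 ratios of HFpEF against L-NAME, 0.33 and 0.57, turned to −0.74 and −0.52 after thinning. The G2 and M phase value against HFD turned from 0.80 to −0.08. These thinned values rest on far fewer UMIs and have wider counting intervals. Compared with the sum of the log2 ratios of both single treatments, the HFpEF log2 ratio to Chow was 2.18 higher for Rnaset2a and 1.21 higher for AC160336.1. For Fcna the HFpEF log2 ratio was lower than that sum, by a difference of −1.29, while Ccl8 differed by −0.06. In endothelial-like cells AC160336.1 was higher too, by 2.10-fold against HFD and 3.76-fold against L-NAME. Rnaset2a was higher there by 5.63-fold against HFD and with 15 UMIs against 0 in L-NAME. Against L-NAME, Hnrnpa0 was also higher in endothelial-like cells (2.72-fold), and Hsp90aa1 (2.61-fold), Dnaja1 (2.34-fold) and Hist1h2ap were also lower.

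Counted per cell and thinned to 500 UMIs, 1 of 150 macrophage-like cells in Chow, 6 of 180 in HFD, 8 of 91 in L-NAME and 5 of 68 in HFpEF had at least 2 UMIs of the G2 and M phase list. In endothelial-like cells, at the same depth, 11 of 132, 4 of 145, 5 of 65 and 2 of 64 cells did. RNA released by other cells was not measured separately and is open as a part of these counts.

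In the cKIT-enriched spleen libraries, erythroid cells and macrophage-like cells were a larger share in HFpEF than in Chow, and most kept cells were B cell-like. Erythroid progenitor- or erythroblast-like cells were 0.837% (0.697 to 0.998%) of kept cells in Chow, 0.0860% in HFD, 1.34% in L-NAME and 2.40% (2.13 to 2.70%) in HFpEF, from 123, 16, 115 and 279 cells. The share ratio to Chow was 2.87 (2.31 to 3.58) in HFpEF, 1.60 (1.23 to 2.08) in L-NAME and 0.103 (0.0570 to 0.174) in HFD. With a minimum of 100 genes per cell the shares were 2.37%, 0.793%, 3.03% and 3.88%, and with predicted doublets kept 1.84%, 0.318%, 2.28% and 3.48%, so the library order held but the ratios were nearer to 1. Cluster 18, the erythroid cluster in which all 11 markers were detected, had 65, 0, 50 and 138 cells. Macrophage-like cells were 3.05%, 2.5%, 9.75% and 8.94%, a ratio to Chow of 3.20 (2.85 to 3.59) in L-NAME and 2.93 (2.62 to 3.28) in HFpEF. Most of that difference lay in cluster 6, of median depth between 614 and 703 UMIs, which held 1.31%, 1.12%, 7.21% and 6.66% of kept cells, and 0.930%, 1.12%, 2.46% and 3.09% with libraries thinned to the same median depth. Monocyte-like cells were 2.61%, 3.70%, 1.32% and 3.30%, neutrophil-like cells 0.238%, 0.113%, 0.210% and 0.568%, and basophil- or mast cell-like cells 0.585%, 0.426%, 0.198% and 0.534%. B cell-like cells were 72.4%, 76.6%, 66.5% and 65.2% of kept cells. Dendritic cell-like clusters held 3.46%, 2.48%, 4.41% and 3.99%, plasma cell-like clusters 2.08%, 1.45%, 2.06% and 1.95%, the T cell-like cluster 2.01%, 2.18%, 1.70% and 2.06%, and the NK or innate lymphoid cell-like cluster 1.15%, 0.939%, 1.23% and 0.913%. Clusters with markers of more than 1 class held 5.41%, 4.84%, 5.01% and 4.57%, and unnamed clusters 5.51%, 4.45%, 5.81% and 5.06%. cKIT bead enrichment can set all of these shares. Kit was detected in 0.735%, 0.550%, 0.617% and 0.612% of kept cells thinned to 500 UMIs and in 4.05%, 2.73%, 3.69% and 3.98% without thinning. In B cell-like cells, which should lack it, the thinned shares were 0.0750%, 0.0140%, 0.00% and 0.0400% at median depths of 1723, 1539, 2575 and 2373 UMIs, and 0 of 5710 cells in L-NAME allows up to 0.0530% of cells with a detected UMI. These shares bound detection at 500 UMIs per cell and not expression.

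**Figure D3:**
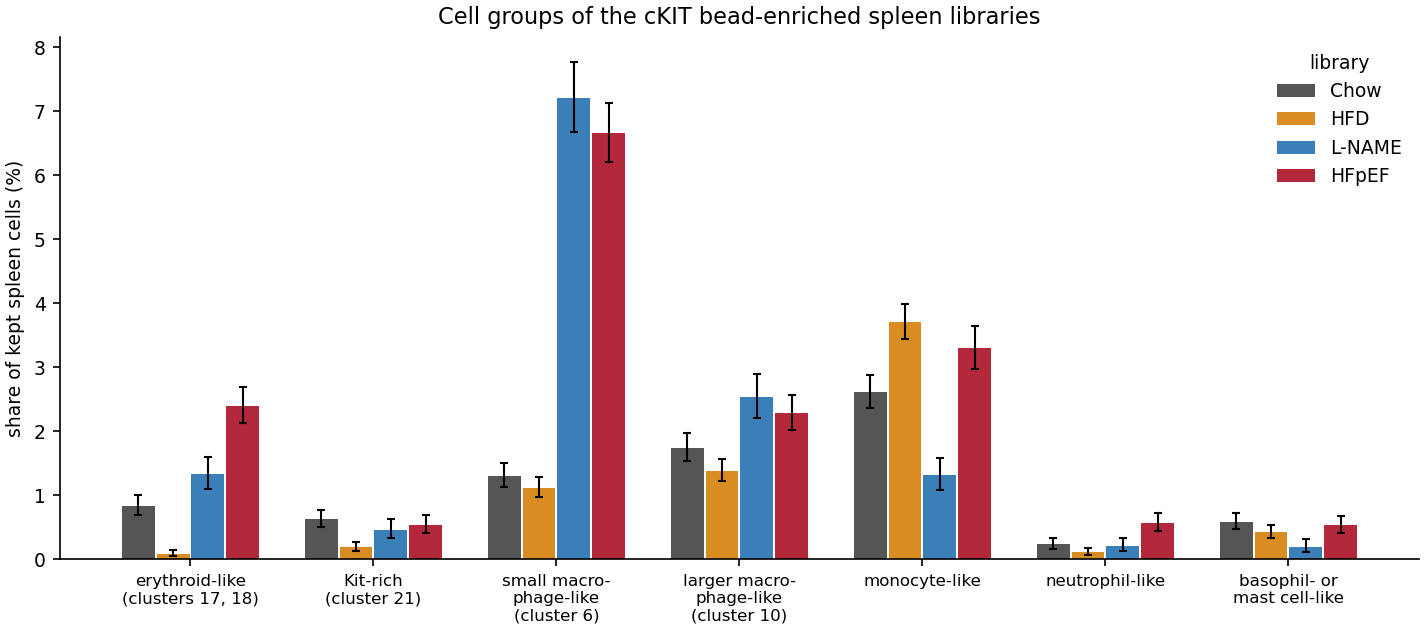
Shares (%) of kept spleen cells in 7 cell groups of the Chow, HFD, L-NAME and HFpEF libraries, as bars from 0 with exact binomial 95% intervals for counting error. Erythroid-like cells stand at 0.837%, 0.0860%, 1.34% and 2.40%, and the small macrophage-like cluster 6 at 1.31%, 1.12%, 7.21% and 6.66%, which were 0.930%, 1.12%, 2.46% and 3.09% at matched depth (not drawn).

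No cluster could be named from the markers planned for stem and multipotent progenitors. Cluster 21, rich in Kit and holding erythroid and stem cell markers, was used in its place and is given by number. It held 92, 36, 40 and 63 cells, or 0.626%, 0.194%, 0.466% and 0.543% of kept cells, and its HFpEF to Chow share ratio was 0.867 (0.619 to 1.21). With under 50 cells in HFD and L-NAME, genes were named only for HFpEF against Chow.

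Within cluster 21, granulocyte and monocyte genes were lower in the HFpEF library, in large part from 3 Chow cells, and Tfrc and Car2 were higher. Myeloid priming genes had 92 UMIs in HFpEF against 1048 in Chow, or 54.6 against 738 CPM, a ratio of 0.0740 (0.0590 to 0.0920), with 10 of 11 members lower. The top 3 Chow cells held 86.7% of the Chow UMIs, and the log2 ratio of −3.75 was −1.67 as a mean over cells and −1.29 after thinning. Mpo, the myeloperoxidase of granulocyte progenitors, had 1 UMI against 285. Tfrc, the transferrin receptor that loads red cell precursors with iron, was 1.79-fold higher (1.51 to 2.15), and Car2, a carbonic anhydrase, 1.46-fold higher (1.38 to 1.54). Median depth was 28305 UMIs in HFpEF and 11343 UMIs in Chow.

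The leading higher genes of cluster 21 included Gstp1 (2.60-fold), Tmem56 (2.57-fold), Hist1h2ap (2.55-fold), Hebp1 (2.28-fold), Ctse (2.10-fold), Ssx2ip (2.09-fold), Paqr9 (2.04-fold), Lmna (1.91-fold) and Erh (1.65-fold). Log2 ratios of Ctse and Paqr9, 1.07 and 1.03, turned to −0.19 and −1.04 after thinning. The leading lower genes were Cd63 (5.43-fold), Nrgn (4.44-fold), Fxyd5 (4.35-fold), Rasgrp2 (3.75-fold), Limd2 (3.64-fold), Tyrobp (3.39-fold), Ly6d (3.21-fold), Tmsb4x (2.75-fold), H2-Aa (2.63-fold) and Cd74 (2.51-fold). After thinning the log2 ratios of Nrgn, Ly6d, Tmsb4x and Tyrobp turned to 0.06, 0.06, 0.00 and 1.62. Nrgn and Ly6d also held very few UMIs at that depth. Markers of other cells were also lower, Nkg7 of NK cells 4.28-fold (3.05 to 6.23) and Cd79a of B cells 2.23-fold (1.75 to 2.86).

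Nuclear genes of oxidative phosphorylation had a ratio of 1.13 (1.11 to 1.16) in cluster 21, with 20 of 22 members higher and a median at the 99.0th percentile. Fatty acid oxidation genes had a ratio of 1.11 (1.05 to 1.18), whose log2 value of 0.15 turned to −0.05 after thinning, and PPAR target genes 1.19 (1.07 to 1.32). The S phase ratio was 1.16 (1.11 to 1.2). The G2 and M phase ratio was 1.15 (1.11 to 1.18), a log2 value of 0.20 that turned to −0.04 with the mitochondrial limit at 10% and to −0.06 with the highest doublet scores removed. MHC class II genes had a ratio of 0.432 (0.4 to 0.466), with 8 of 8 members lower. B cell markers were also lower in cluster 21, at 375 CPM in HFpEF against 705 CPM in Chow. RNA of B cells is therefore not set apart from expression in cluster 21 for the MHC class II genes. Cholesterol genes had a ratio of 0.565 (0.506 to 0.630), stem cell quiescence genes 0.734 (0.648 to 0.831), lymphoid priming genes 0.610 (0.535 to 0.695), and cytokine receptor and adhesion genes 0.780 (0.724 to 0.840). Megakaryocyte and erythroid priming genes had a ratio of 1.06 (1.02 to 1.10), whose log2 value of 0.09 turned to −0.06 after thinning, and haemoglobin genes 1.77 (1.49 to 2.11). Haemoglobin genes made up 2.89% of all UMIs in the HFpEF spleen library and 0.708% in Chow, so RNA of other cells is not set apart from expression in cluster 21.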

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

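The test on haemoglobin RNA was fixed before its result was seen, and the tests on depth and on the Kit-rich cluster were chosen afterwards. Erythroid-like cells of the spleen differed in opposite directions with the high-fat diet without and with L-NAME. Their share had a ratio of 0.103 in HFD against Chow and of 1.79 (1.44 to 2.25) in HFpEF against L-NAME, and the difference between these was not tested. With a minimum of 100 genes the shares were 2.37% (Chow), 0.793% (HFD), 3.03% (L-NAME) and 3.88% (HFpEF), which keeps both directions but brings both ratios nearer to 1. A class was flagged where both ratios were at least 1.5-fold from 1, with intervals on opposite sides of 1. Of the 16 classes checked in both organs, only erythroid-like and neutrophil-like cells of the spleen were flagged. Spleen basophil- or mast cell-like cells had ratios of 0.728 (0.530 to 1.00) in HFD against Chow and 2.70 (1.56 to 4.92) in HFpEF against L-NAME. The first of these fell short of 1.5-fold.

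For the higher erythroid share in HFpEF than in Chow, 3 technical explanations were weighed. A first depth test thinned libraries to the same median but kept each cell's cluster, so it could hardly move these deep cells and is set aside. Depth per cell and free haemoglobin RNA are both argued against by the 9 other erythroid markers with every cell thinned to 500 UMIs. At least 3 of their UMIs were seen in 2.059% (1.81 to 2.33%) of HFpEF cells, against 0.885% (0.740 to 1.05%) in Chow, 0.0380% in HFD and 1.18% in L-NAME. Stronger cKIT enrichment in the HFpEF library predicted more Kit-rich cells, and the share ratio of cluster 21 was 0.867 (0.619 to 1.21). With a minimum of 1000 UMIs, however, its shares were 1.08% in HFpEF and 0.848% in Chow. Stem and progenitor markers, Kit among them, were in a mean share of 0.282 of its cells. In the erythroid-like clusters 17 and 18 that share was 0.045 and 0.066. This test therefore does not decide whether bead enrichment set the erythroid share. A response of splenic red cell production to the treatments may remain as a hypothesis. So may differences in animals, bead enrichment or red cell lysis between single preparations, which 1 library per group leaves confounded with that response.

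Neutrophil-like cells had a ratio of 0.475 (0.263 to 0.840) in HFD against Chow and of 2.70 (1.59 to 4.85) in HFpEF against L-NAME, from 21 and 35 and from 66 and 18 cells, and this difference was not tested. Among heart barcodes above the mitochondrial limit, which no comparison used, at least 5 UMIs of macrophage markers were found in 206 of 11033 (Chow), 133 of 4288 (HFD), 198 of 15018 (L-NAME) and 15 of 505 (HFpEF).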

How the results depend on the processing

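Over the alternatives run for each kind, 326 of 428 class shares, 1011 of 1363 list ratios, 729 of 852 ratios of named genes and 245 of 434 shares of cells with a UMI or cycle call stayed within the counting interval of the value first given. Reversals numbered 34 list ratios and 12 gene ratios. Thinning to 500 UMIs was the least stable for ratios, with 49 of 143 list ratios and 27 of 88 gene ratios staying and 18 and 8 reversed. Thinned values rest on far fewer UMIs than the values first given, and their wider counting intervals are not given. List medians were recomputed only for members with at least 50 UMIs, and 116 of 116 stayed within an interval taken from the spread among members. Those members are part of the same lists, so this says little about stability. The limit of 40% mitochondrial UMIs, removal of the highest doublet scores and equal cluster weights were chosen after seeing the data. With at most 10% mitochondrial UMIs, too few heart macrophage-like cells were left for values against Chow. In that setting 51 heart barcodes of the Chow library passed the limits, and Scrublet removed 28 of them as doublets. Cluster 21 was not recovered with doublets kept or with a minimum of 100 genes. As all barcodes held 500 UMIs, the minimum of 250 had no effect. The mitochondrial limit removed 63.5% to 97.8% of barcodes in the heart libraries. No paired analysis was possible because each group had 1 pooled library. The cause of a move between settings was not tested.

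Cells thinned to 500 UMIs, in heart macrophage-like cells, gave log2 ratios of −0.024 (HFD), 0.37 (L-NAME) and −0.37 (HFpEF) for fatty acid oxidation and −0.74 for HFpEF against L-NAME. For the G2 and M phase list they gave 2.09 (L-NAME), 1.57 (HFpEF), −0.078 for HFpEF against HFD and −0.52 against L-NAME, and 0.058 for L-NAME in endothelial-like cells. Interferon response gave 0.032 (L-NAME) and 0.078 (HFpEF), the unfolded protein response 0.23 and immunoglobulin genes −0.096 (both L-NAME), myeloid priming 0.11 and Stmn1 −0.082 (both HFD), immediate early genes −0.13 (HFpEF), and Il1b −0.23 (HFpEF against HFD). In cluster 21, HFpEF against Chow, thinning gave −0.045 for fatty acid oxidation, 1.77 for resident macrophage, 0.11 for pro-fibrotic, 0.55 for niche, 0.92 for immediate early, −1.29 for myeloid priming and −0.056 for megakaryocyte and erythroid priming genes. It gave −0.19 for Ctse, −1.04 for Paqr9, 0.061 for Nrgn, 0.061 for Ly6d, 0.002 for Tmsb4x and 1.62 for Tyrobp. Ctse, Paqr9, Nrgn and Ly6d held very few UMIs at that depth.

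Means over cells gave 1.34 (HFD) and 1.93 (HFpEF) for G2 and M phase, −0.028 for immediate early genes (HFpEF) and −0.41 for Il1b (HFpEF against HFD) in macrophage-like cells, and 0.053 for G2 and M phase in endothelial-like cells (L-NAME). In cluster 21 they gave 0.30 for inflammatory, 2.01 for resident macrophage, 0.039 for lipid-associated, 0.67 for niche, 0.77 for immediate early and −1.67 for myeloid priming genes, 0.37 for Tmsb4x and 1.42 for Tyrobp. Totals without abundant gene groups gave −0.002 for immediate early genes (HFpEF). Equal weights for clusters 2, 4 and 7, with cluster 10 left out, gave −0.056 for recruited macrophage genes (HFD), 0.007 for interferon response and −0.096 for MHC class II (L-NAME), and 1.28, 2.68 and 2.77 for G2 and M phase.

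A limit of 40% mitochondrial UMIs gave a Chow macrophage share of 26.6%, and G2 and M phase values of 1.33 (L-NAME) and, in endothelial-like cells, 0.023 (HFpEF). A limit of 10% gave 0.26 for Lyz1 (HFpEF against HFD), and in the spleen a cluster 21 share of 0.77% in Chow and −0.035 for its G2 and M phase list. Removing the highest doublet scores gave −0.059 for that list and 0.39 for heart PPAR targets (L-NAME), and keeping doublets gave 0.33. A minimum of 1000 UMIs gave cluster 21 shares of 0.848% (Chow) and 1.08% (HFpEF). Erythroid shares were 2.37%, 0.793%, 3.03% and 3.88% with a minimum of 100 genes, and 1.84%, 0.318%, 2.28% and 3.48% with doublets kept. Cells of cluster 21 and other cells joined the erythroid class in both.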

Other observations

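Spleen monocyte-like cells had higher lipid uptake and PPAR target genes in each treated library than in Chow. Both lists hold Cd36, Fabp4 and Plin2, so they are not separate results. These cells formed a single cluster, led by genes that include Ccr2, Ace and Cx3cr1, and monocyte subsets within it were not examined. PPAR target genes had ratios of 1.78 (1.68 to 1.88) in HFD, 1.36 (1.25 to 1.48) in L-NAME and 1.40 (1.32 to 1.49) in HFpEF, with list medians at the 100th, 97.4th and 99.8th percentiles. Fatty acid uptake and lipid storage genes had ratios of 1.73 (1.62 to 1.85), 1.49 (1.35 to 1.63) and 1.42 (1.32 to 1.52). Cd36 was 2.69-fold, 2.07-fold and 1.99-fold higher, and Fabp4, a fatty acid chaperone, 2.98-fold, 2.03-fold and 2.39-fold. Fatty acid oxidation genes had ratios of 1.11 (1.03 to 1.2), 1.04 (0.918 to 1.17) and 1.02 (0.937 to 1.11) in the same cells. Haemoglobin genes stood at 28.9, 102 and 843 CPM in these cells against 82.8 CPM in Chow, which marks RNA of other cells in the HFpEF library.

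Spleen B cell-like cells had higher immediate early and heat shock genes in each treated library. Dissociation and immediate early genes had ratios to Chow of 2.03 (2.01 to 2.05) in HFD, 1.24 (1.22 to 1.25) in L-NAME and 1.54 (1.53 to 1.56) in HFpEF, and heat shock genes 1.56 (1.55 to 1.57), 1.31 (1.30 to 1.32) and 1.26 (1.25 to 1.27). Egr1, an immediate early transcription factor, was 4.44-fold, 2.49-fold and 2.15-fold higher, and Hspa1b, an inducible HSP70 gene, 2.59-fold, 1.59-fold and 1.79-fold. These lists also respond to tissue handling, so handling of each spleen is open beside the treatments.

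Tests that split the leading higher genes of the heart, and that on the joint macrophage share, were chosen after the result was seen. The others were fixed before their results were seen, but the equal cluster weights were chosen after seeing the data. A first test over all 10 higher genes gave an endothelial median log2 ratio of 1.33 against 2.30 in macrophage-like cells and decided nothing. For the 7 higher genes outside the G2 and M phase list, the endothelial median was 1.944 and the macrophage median 2.38. Of these, Stmn1 was lower in endothelial-like cells (log2 −1.88, −2.92 to −1.02). The other 6 were higher in both classes with intervals above 1, which goes with a difference between whole libraries. A treatment effect on both classes and a difference between preparations are not told apart for them. For the 3 genes of the G2 and M phase list the endothelial median was −4.802 against 2.21. However, Mki67 and Top2a had 0 UMIs there in HFpEF and the Chow class held haemoglobin RNA of other cells. A difference of whole libraries therefore stays open for these 3 genes. For the 10 lower genes a different mix of macrophage clusters is argued against, since the median of −1.40 was −1.167 with clusters 2, 4 and 7 weighted equally and cluster 10 left out, and a treatment effect and a difference between preparations stay open.

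Small macrophage-like cells (cluster 6) were a larger share of the spleen in the L-NAME and HFpEF libraries. Depth per library as the whole cause is argued against, since at matched depth, with each cell's cluster kept, the lower of the ratios to Chow was 2.647 (2.12 to 3.32). It is still part of the difference, because matching took the shares from 1.31%, 1.12%, 7.21% and 6.66% to 0.930%, 1.12%, 2.46% and 3.09%. Passage of cells from the larger macrophage cluster by loss of RNA is argued against, since both clusters together had a ratio to Chow of at least 2.931 in these libraries, and of 1.93 (1.68 to 2.23) in L-NAME and 2.04 (1.79 to 2.33) in HFpEF at matched depth. L-NAME, given to the mice of both libraries, may account for the share, as may a difference in dissociation shared by both preparations, which the design leaves confounded with it.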
